A study of Homo sapiens with 2 samples.

How the data were processed

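REST CUT&Tag was performed in primary human aortic endothelial cells with a commercial kit, and 2 libraries of 1 group were used. They are called replicate 1 and replicate 2 here after the numbers in their titles, which do not use the word replicate. Per the submitters' processing notes, the tools were Bowtie2 and MACS2 and the genome build was hg38, and no versions, thresholds or control library are given in the sources used here. The deposited files are peak lists called in each library separately. For each peak the authors give the fold enrichment at the summit, a ratio of signal to local background, and the −log10 of a p-value and of a q-value, as MACS2 writes them. Read totals are not given, so depth is unknown, and a difference in peak number can follow from depth, antibody efficiency or background alike. A deeper library gives more peaks at a fixed threshold. Fold enrichment was therefore used only within each list, to describe, rank, filter, match or compare its peaks. A cut-off at the same fold enrichment or q in both lists, used among the alternatives, need not be equally strict in both. Wilson intervals for shares of peaks cover counting error only.

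Coordinates were written 1-based. Peaks on chromosomes 1 to 22 and X were used. Peaks on chromosome Y were left out throughout, and peaks on unplaced or alternate contigs and the mitochondrion were left out of the main results. Genes came from the RefSeq table of the matching assembly, restricted to 19821 protein-coding genes on these chromosomes. Rows of scaffold genes, which carry the name of a chromosome but scaffold coordinates, were removed. The table holds no strand and no exons, so the planned distances to a transcription start were measured to the nearer of the start and end of each gene, and positions are given as inside or outside a gene. No genome sequence was used, so the planned search for the RE1 element, the sequence REST binds, was not run.

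A replicate 2 peak was shared when it overlapped a replicate 1 peak by at least 1 bp. The overlap was compared with 1000 random placements of the replicate 2 peaks within the annotated span of their chromosome, and the share of summits within 1 kb of a gene end with 1000 such placements, in one-sided permutation tests. The merged set held all replicate 1 peaks and the replicate 2 peaks that did not overlap them. For 17 gene lists and 20 gene families, chosen before the data were examined, members with a summit within 5 kb of either gene end were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over all 37. Differences in percentile or fold enrichment were tested with two-sided permutation tests of means, with 100000 resamples for shared against other peaks and 20000 for gene lists, adjusted over the lists with at least 5 genes.

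The genes and peaks named were set by a rule fixed before the data were examined. They were the 15 shared peaks of best mean rank within 5 kb of a gene end, the 5 of best mean rank farther away, up to 4 members of each list past the threshold and of the endothelial, mesenchymal, inflammation and shear lists, REST and RCOR1, and the 5 strongest replicate 2 peaks without a partner. Within lists, members with shared peaks came first and then those of higher replicate 1 fold enrichment. The recovery of replicate 1 peaks by strength and the share of peak-bearing genes with a shared peak, which was not matched on strength, were added after the data were seen, and NEUROD1, NEUROG3, POU4F2 and SRRM3 were named after their values were seen.

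Alternatives fixed beforehand were stricter peaks, contigs kept, other definitions of overlap, other windows, the peak midpoint, assignment to the nearest gene, shared peaks alone, matched placements and leaving out each library. Alternatives added later left out regions prone to repeats, known REST targets or unnamed and read-through genes, shifted peaks locally, or used gene bodies against 10000 lists matched on gene length. Regions prone to repeats were summits within 100 kb of the outermost annotated gene of a chromosome, within 5 kb of a nuclear pseudogene of a mitochondrial gene, or more than 100 kb from any annotated gene. They were set by position in the gene table and not by sequence, so other repeats may lie outside them. Recovery expected from strength was drawn from the 100 replicate 1 peaks nearest in fold rank, outside those regions and the compared lists, with 100000 simulated draws.

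Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with figures drawn in matplotlib 3.10.9. The tests were checked on simulated data. For the comparison of a gene list with all other genes in the merged set of 19821 genes, a planted odds ratio of 3 was called at an unadjusted p under 0.05 in 58% of 200 simulated lists of 20 genes and in 85.5% of lists of 40 genes, and a planted odds ratio of 1 in 3.5% and 3%.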

Results

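CUT&Tag, in which an antibody directs a transposase to insert sequencing adapters beside a chromatin protein, was used to map REST in human aortic endothelial cells, the cells that line the aorta, grown as a primary culture. REST is a zinc finger repressor best known for silencing neuronal genes outside the nervous system. The series held 2 libraries of 1 group, both assigned to batch 1, and no untreated or control antibody library was analysed here. The question was which promoters and other regulatory regions of these cells carry REST. The labels do not say whether the libraries came from separate cultures, so the spread between them may be technical. The files list peaks without read totals, so the depth of each library is unknown.

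Replicate 1 had 4304 peaks on chromosomes 1 to 22 and X and replicate 2 had 295, a 14.6-fold difference in number. The replicate 1 peaks had a median width of 224 bp and covered 1167 kb, and the replicate 2 peaks had a median width of 191 bp and covered 71.9 kb. The median fold enrichment over local background, the authors' own value for each peak, was 6.02 in replicate 1 (range 3.06 to 30.1) and 6.69 in replicate 2 (range 3.68 to 24.6). The median −log10 q was 4.64 in replicate 1 and 5.06 in replicate 2. Peak names in the replicate 2 list began with REST15, a number that differs from the one in the title of that library.

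Most replicate 2 peaks had a partner in replicate 1. Of the 295 replicate 2 peaks, 247 overlapped a replicate 1 peak by at least 1 bp, a share of 83.7% (95% Wilson interval 79.1% to 87.5%). Random placements of the same peaks on their chromosomes overlapped replicate 1 a mean of 0.292 times (SD 0.574, at most 3 in 1000 placements; one-sided permutation p = 0.001, the smallest that 1000 placements can give). Placements kept at the same distances from gene ends gave a mean of 3.74 overlaps and at most 13. The other 48 had no partner, and when each peak had to cover at least 50% of the other, 133 of the 295 were shared. The 247 peaks corresponded to 245 replicate 1 peaks, 5.69% of that list.

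The replicate 1 peaks found again in replicate 2 were mainly strong ones. With the list cut into 5 equal parts by fold enrichment, the strongest part had fold enrichment of 7.45 or more, and 172 of its 860 peaks (20%, 95% Wilson interval 17.5% to 22.8%) overlapped a replicate 2 peak. The share was 5.11% in the next part (interval 3.83% to 6.79%) and 1.05% in the weakest (interval 0.551% to 1.97%). The mean percentile of fold enrichment within replicate 1 was 82.5 for the 245 shared peaks and 48.0 for the 4059 others (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give).

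**Figure D1:**
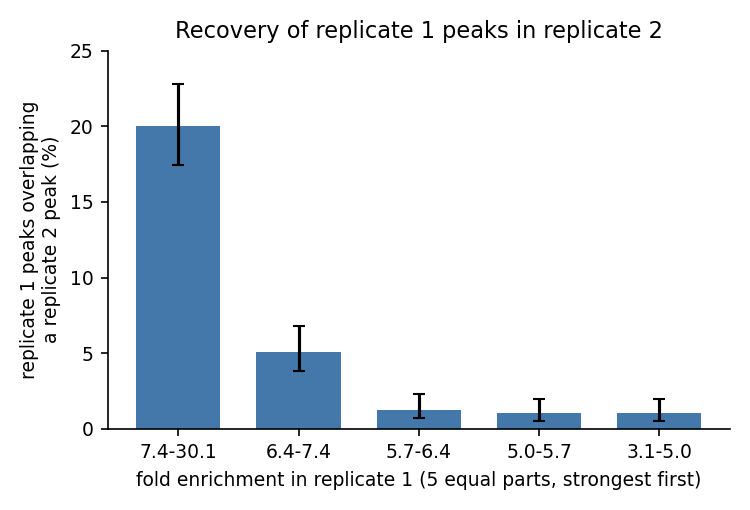
Share of replicate 1 peaks that overlap a replicate 2 peak (y axis, percent) in 5 equal parts of the list by replicate 1 fold enrichment (x axis, strongest first); bars give the share and lines the 95% Wilson interval. The share was 20% in the strongest part and 1.05% in the weakest.

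Of the genes that name the 15 shared peaks of best mean rank within 5 kb of a protein-coding gene end, 2, DRD2 and CPLX2, were on the fixed list of known REST targets and 1, RAB37, was in the RAB family. Of the 15, 6 are described here, chosen after their values were seen. A peak at DRD2, which encodes a dopamine receptor, spanned positions 113474126 to 113474862 of chromosome 11 (hg38), inside the gene and 820 bp from its end, with fold enrichment of 12.5 in replicate 1 and 10.3 in replicate 2. HTR5A, a serotonin receptor gene, had a peak on chromosome 7 from 155069798 to 155070358, outside the gene and 141 bp from its end, at 13.7 and 9.49. CPLX2, whose product complexin controls synaptic vesicle fusion, had one on chromosome 5 from 175796575 to 175797284, inside the gene, at 11.4 and 9.35. SVOP, a synaptic vesicle protein gene, had one on chromosome 12 from 109020896 to 109021160, inside the gene, at 13.2 and 7.71. RAB37, a small GTPase gene, had one on chromosome 17 from 74671103 to 74671646, inside the gene, at 13.7 and 11.0. KCNIP2, a potassium channel partner gene, had one on chromosome 10 from 101840800 to 101841471, inside the gene and 2863 bp from its end, at 11.5 and 10.3.

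The other members of the 15 were the peaks next to SPATC1L, SERINC2, CYB5R4, SEC14L5, GDAP1, GSX1, IQSEC3, MSH3 and RNF141. Across the 15, fold enrichment ran from 11.3 to 15.8 in replicate 1 and from 7.71 to 16.4 in replicate 2. The SPATC1L peak on chromosome 21, from 46184486 to 46184761, reached 15.3 in replicate 1 and 11.2 in replicate 2. The homeobox gene GSX1 had its peak 76 bp from the gene end, inside the gene, at 11.3 and 8.28. The peaks named by MSH3 and RNF141 lay within 5 kb of nuclear copies of mitochondrial genes, and the IQSEC3 peak lay within 100 kb of the outermost annotated gene of chromosome 12, which are places where reads can map ambiguously. REST itself had a shared peak on chromosome 4 from 56908310 to 56908838, inside the gene and 520 bp from its end, at 8.35 and 6.29. RCOR1, which encodes the REST corepressor CoREST, had no peak within 5 kb in either library.

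Peaks were concentrated at the ends of protein-coding genes. In replicate 1, 2528 of 4304 summits (58.7%, 95% Wilson interval 57.3% to 60.2%) lay within 1 kb of a gene end, against 3.12% of randomly placed summits. In replicate 2 the share was 34.9% (103 of 295, interval 29.7% to 40.5%) against 2.99%, and in the merged set of 4352 peaks it was 58.3% against 3.11% (one-sided permutation p = 0.001 for each set, the smallest that 1000 placements can give). Of the shared peaks, 38.0% lay within 1 kb, 24.9% lay farther away inside a protein-coding gene and 37.1% lay between genes. Peaks found in replicate 1 alone lay within 1 kb more often, at 60.0% (odds ratio 2.45 against shared peaks, 95% interval 1.87 to 3.23, two-sided Fisher's exact p = 1.99e-11). Regions prone to repeats held 17.1% of shared peaks and 1.43% of peaks in replicate 1 alone. The odds ratio was not computed without these regions, so part of the difference may come from them. The gene table gives no strand, so a gene end here is either a transcription start or a transcription end.

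**Figure D2:**
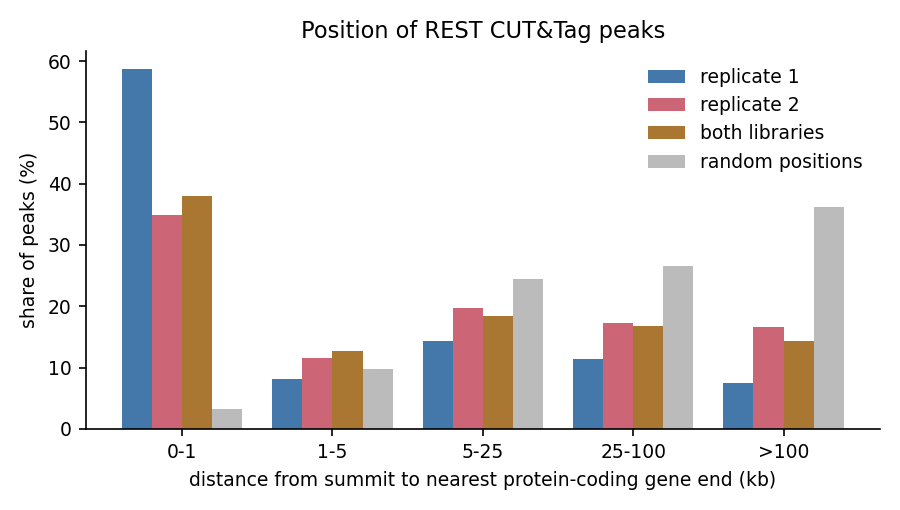
Share of peaks (y axis, percent) by distance from the summit to the nearest protein-coding gene end (x axis, kb) in replicate 1, in replicate 2, in the peaks found in both libraries and at random positions. Within 1 kb lay 58.7% of replicate 1 peaks, 34.9% of replicate 2 peaks, 38.0% of shared peaks and 3.18% of random positions.

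Of 19821 protein-coding genes, 3641 (18.4%) had a summit within 5 kb of either end in the merged set. The number was 3629 in replicate 1, 177 in replicate 2 and 164 among shared peaks. Of the 37 gene lists and families fixed before the data were examined, 6 had peaks more often than all other genes and 3 less often, at a Benjamini-Hochberg adjusted p under 0.05 in Fisher's exact tests.

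Genes known as REST targets from other cells had the highest share. A peak lay near 31 of 52 (59.6%) against 18.3% of all other genes (odds ratio 6.61, 95% interval 3.67 to 12.1, two-sided Fisher's exact test, adjusted p = 8.36e-10). For 12 of the 52 the peak was in both libraries (odds ratio 38.7, interval 18.1 to 77.0, exact adjusted p = 3.93e-13). Of the listed genes with a peak, 38.7% had a shared one, against 4.21% of other genes with a peak (Fisher's exact p = 3.14e-09). The 4 members leading the list were DRD2 and CPLX2, described above, and RAB3C and SNAP25. RAB3C, a synaptic vesicle GTPase gene, had a peak on chromosome 5 from 58582722 to 58583249, inside the gene, with fold enrichment of 11.0 in replicate 1 and 4.34 in replicate 2. Its replicate 2 peak had a −log10 q of 1.31, the lowest in that list. SNAP25, a gene of the membrane fusion complex, had one on chromosome 20 from 10219442 to 10219851, inside the gene, at 10.4 and 6.51. The best replicate 1 peaks of the listed genes were also stronger, with a median fold enrichment of 7.79 against 6.18 for all genes with a peak (two-sided permutation p of the difference in means 5e-05, adjusted p = 0.00085).

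Synaptic vesicle release genes had a peak in 15 of 41 cases (36.6%, odds ratio 2.57, 95% interval 1.26 to 5.04, Fisher's exact test, adjusted p = 0.0323). Of these, 4 were shared, at CPLX2, RAB3C, SNAP25 and SYN1, and the SYN1 peak had fold enrichment of 5.83 in replicate 1 and 6.58 in replicate 2. Neuroendocrine granule and peptide genes had a peak in 11 of 28 (39.3%, odds ratio 2.88, interval 1.22 to 6.53, exact adjusted p = 0.046). CRH, encoding corticotropin-releasing hormone, had a shared peak on chromosome 8 from 66177033 to 66177770 at 10.1 and 7.70. The granule protein genes CHGB and SCG3 had shared peaks at 8.60 and 8.57 in replicate 1, and the somatostatin gene SST had one in replicate 1 alone at 9.72. Neither list passed without its members that are also known REST targets, 12 of 41 and 8 of 28 genes (odds ratios 1.17 and 0.79, exact adjusted p = 0.851 and 1). With a window of 1 kb the synaptic list reached an odds ratio of 2.36 (exact adjusted p = 0.0632) and the neuroendocrine list 2.28 (exact adjusted p = 0.179), and at 25 kb the neuroendocrine list reached 2.05 (exact adjusted p = 0.178), so these calls were lost. Both calls held with higher odds ratios in replicate 2 alone (12.2 and 13.5, exact adjusted p = 0.00593 and 0.018), among shared peaks (13.2 and 14.6, exact adjusted p = 0.00445 and 0.0145) and at −log10 q of at least 5 (4.25 and 5.71, exact adjusted p = 0.00152 and 0.00111). However, 0 of the 29 synaptic and 0 of the 20 neuroendocrine genes outside the known REST targets had a shared peak. The calls among shared peaks therefore rest on known REST targets alone and repeat that result. Replicate 2 alone had peaks near the same numbers of genes, 4 and 3. Neuronal transcription and splicing regulators did not pass in the merged set, with 11 of 39 (odds ratio 1.75, exact adjusted p = 0.309). They passed among shared peaks, with 4 genes, NEUROD1, NEUROG3, POU4F2 and SRRM3 (odds ratio 14, interval 3.57 to 39.8, exact adjusted p = 0.00445).

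Housekeeping, histone and RAB genes also had peaks more often than the rest. Broadly expressed housekeeping genes had a peak in 14 of 30 cases (46.7%, odds ratio 3.90, 95% interval 1.76 to 8.53, Fisher's exact test, adjusted p = 0.00335), and 0 of the 14 genes had a shared peak. Of other genes with a peak only 4.52% had a shared one, so 0 of 14 does not set these genes apart. The call was lost at −log10 q of at least 5 (odds ratio 2.05, exact adjusted p = 0.499), with a window of 1 kb (2.86, exact adjusted p = 0.0566) and for summits inside gene bodies (1.64 times the length-matched mean, permutation adjusted p = 0.762). The leading members were SNRPD3, EEF2, TFRC and PSMB2, with replicate 1 fold enrichment of 8.0, 7.77, 7.66 and 7.26. Histone genes had a peak in 24 of 73 (odds ratio 2.18, interval 1.28 to 3.63, exact adjusted p = 0.0181), but the 24 genes shared 12 peaks, so they are not independent. The histone call was lost with a window of 1 kb (odds ratio 2.01, exact adjusted p = 0.0581) and at fold enrichment of at least 5 (1.92, exact adjusted p = 0.08). It was also lost for summits inside gene bodies (2.32 times the matched mean, permutation adjusted p = 0.469), and the odds ratio was below 1 at −log10 q of at least 5 (0.915) and by nearest gene (0.845). H4C4 and H2BC6 had the same peak, at 7.71, and H2AC11 and H2AC15 had peaks at 6.86. RAB GTPase genes had a peak in 22 of 63 (odds ratio 2.39, interval 1.36 to 4.12, exact adjusted p = 0.0101), or an odds ratio of 2.19 (exact adjusted p = 0.0414) without RAB3A and RAB3C, which are also known REST targets. The RAB call was lost for summits inside gene bodies (1.62 times the matched mean, permutation adjusted p = 0.422). Of these, RAB37 and RAB3C were shared, and RAB39A and RAB3A had peaks in replicate 1 alone at 12.5 and 8.72. Without replicate 1, where 177 genes had a peak, none of these 3 groups passed, with odds ratios of 0, 0 and 3.67.

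Peaks were rarer near HOX genes (0 of 39, exact adjusted p = 0.00448), olfactory receptor genes (1 of 387, OR2T1, odds ratio 0.0112, exact adjusted p = 1.92e-31) and keratin genes (1 of 55, KRT19, odds ratio 0.082, exact adjusted p = 0.00335). The HOX and keratin calls were lost at −log10 q of at least 5 (exact adjusted p = 0.17 and 0.0656) and inside gene bodies (permutation adjusted p = 0.469 and 0.174). Under these settings 0 genes of either family had a peak, so the counts were at their floor. Fewer genes had any peak at the stricter q (1766 in place of 3641), and inside gene bodies only 2.26 HOX and 3.57 keratin genes were expected. Neither setting therefore shows whether the deficit changed. The keratin call was also lost by nearest gene (odds ratio 0.336, exact adjusted p = 0.0643). Among shared peaks and in replicate 2 alone, 0 genes of the 3 families had a peak, and too few genes had any for a deficit to pass. Members of these families lie in clusters, so their genes are not independent. Few endothelial identity genes had a peak within 5 kb. No peak of this list or of the mesenchymal, inflammation or shear lists was shared, but only 4.51% of other genes with a peak had a shared one. With so few listed genes bearing a peak, the absence of a shared one tells little. Endothelial identity genes had a peak in 2 of 40 cases, NOS3 and HEY2 (odds ratio 0.233, 95% interval 0.0273 to 0.904, Fisher's exact p = 0.024, adjusted p = 0.0803). The deficit did not pass the threshold. It was larger with a window of 1 kb (odds ratio 0.146, exact adjusted p = 0.0883) and at fold enrichment of at least 5 (0.139, exact adjusted p = 0.0638). It was smaller at 25 kb (odds ratio 0.685, exact adjusted p = 0.574) and absent by nearest gene at any distance (1.07, exact adjusted p = 0.914). The NOS3 peak, near the endothelial nitric oxide synthase gene, lay on chromosome 7 from 150988709 to 150989024, outside protein-coding genes, with fold enrichment of 5.13 in replicate 1. Mesenchymal genes, which rise when endothelial cells lose their identity, had a peak in 5 of 40 (odds ratio 0.634, exact adjusted p = 0.644), led by SPARC at 7.35, SMAD2 at 5.98, TGFBR2 at 4.86 and VIM at 4.73. By nearest gene at any distance the mesenchymal odds ratio was 1.25 (exact adjusted p = 0.651). It was 0.286 at fold enrichment of at least 5 (exact adjusted p = 0.192) and 0.262 at −log10 q of at least 5 (exact adjusted p = 0.563). Inflammation and adhesion genes had a peak in 2 of 30, RELB at 8.72 and NFKB1 at 5.17 (odds ratio 0.317, exact adjusted p = 0.309). Genes responsive to shear or acting on vessel tone had a peak in 5 of 23 (odds ratio 1.23, exact adjusted p = 0.746), led by KCNJ2 at 6.53, PPP1R16B at 5.47, NQO1 at 5.44 and NOS3. The shear odds ratio was 2.17 at 25 kb (exact adjusted p = 0.18), 2.77 by nearest gene (exact adjusted p = 0.0672), 5.07 without replicate 1 (exact adjusted p = 0.569) and 0.939 without replicate 2, and the list passed under no setting. No member of the smooth muscle (0 of 17) or fibroblast (0 of 14) lists had a peak, and 2 of 18 leukocyte markers did.

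**Figure D3:**
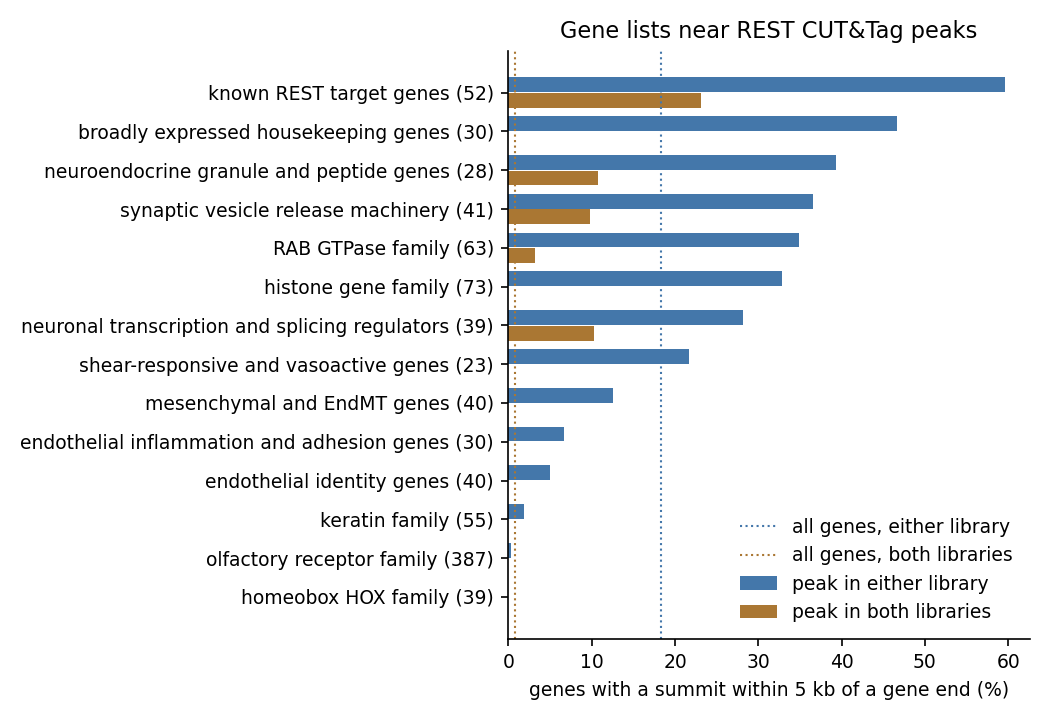
Share of genes with a summit within 5 kb of a gene end (x axis, percent) for lists and families, with the number of genes in parentheses; bars show peaks in either library and in both, and dotted lines show the shares of all protein-coding genes. Known REST targets reached 59.6% in either library and 23.1% in both, and housekeeping genes reached 46.7% and 0%.

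Several of the strongest shared peaks lay far from protein-coding genes. The peak with the highest fold enrichment in both libraries was on chromosome 13 from 109424138 to 109424380, at 30.1 and 24.6. Its nearest protein-coding gene end, of MYO16, was 216264 bp away. It lay outside the regions defined as prone to repeats, but those were set by position and no sequence was used. A pile-up of reads at this site was therefore not excluded, and the peak was not shown to be a REST site. A peak on chromosome 3 from 93470367 to 93470825 reached 22.9 and 20.7, in a stretch with no annotated gene within 100 kb, 402511 bp from PROS1. The other leading distant peaks lay within 100 kb of the outermost annotated gene of their chromosome, near RABL2B on chromosome 22 (19.1 and 21.3), IL9R on chromosome X (13.9 and 16.6) and PARD6G on chromosome 18 (13.7 and 20.1). Of the 48 replicate 2 peaks without a replicate 1 partner, the 5 of highest fold enrichment were an intragenic peak of LRRC27 at 12.2 and peaks nearest to ZNF595 (10.9), OTULINL (8.41), PRMT2 (7.85) and ZNF33B (7.56). The ZNF595 and PRMT2 peaks lay near chromosome ends and the ZNF33B peak in a gene-poor stretch.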

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

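The test of recovery against strength in this part was chosen after the positions of the strong peaks had been seen. Peaks outside the chromosomes used in the report drew attention because they form a signal in data outside the main results. Among the results described here, they entered only the alternative peak and overlap counts. Replicate 1 had 135 peaks on contigs and the mitochondrion, 3.04% of its peaks, and replicate 2 had 35, 10.6% of its peaks. Of these, 3 and 6 lay on the mitochondrial genome.

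Shared peaks at chromosome ends, mitochondrial pseudogenes and gene-poor stretches, some of them strong, formed the pattern weighed here. As a set they were not stronger in replicate 1 than other shared peaks (median fold enrichment 7.99 against 8.57). The median was 9.41 at chromosome ends, 7.20 in gene-poor stretches and 4.78 at mitochondrial pseudogenes. For all replicate 2 peaks the medians were 7.48 in these regions and 6.60 elsewhere. These regions held 100 replicate 1 peaks, and 42 of them were found again in replicate 2, where 9.30 were expected from replicate 1 peaks nearest in fold rank (SD 2.42, at most 20 in 100000 simulated draws). At mitochondrial pseudogenes 7 of 9 were found again, at chromosome ends 21 of 37 and in gene-poor stretches 14 of 54. Some of these peaks lie close together, as between positions 629333 and 634172 of chromosome 1, so they are not independent. The simulated draws treated them as independent, so their SD may be too small. The regions were defined after strong shared peaks had been seen there, so the excess can follow in part from that choice. Reads from repeated sequence piling up in any library would also give it. A pile-up of this kind may account for these peaks, but the test does not establish it. Peaks near known REST targets were also found again more often than their strength predicted, so the excess does not by itself exclude REST at these sites, and without a control library or the underlying sequence no biological explanation was tested.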

How the results depend on the processing

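Leaving out regions prone to repeats, unnamed and read-through genes or known targets, the gene-body assignment, the local shift and the recovery settings were chosen after the data were seen. The enrichment of known REST targets stayed past its threshold under every alternative run on it, as did the share of summits near gene ends. The odds ratio of known targets ran from 5.86 at 25 kb to 38.7 among shared peaks. At −log10 q of at least 5 there were 1910 and 152 peaks, 136 of them shared, and 1766 genes, since fewer peaks entered. A reciprocal overlap of 50% left 133 shared peaks. A window of 25 kb gave 5895 genes, and one of 1 kb left 5 lists past the threshold in place of 9. Shared peaks alone gave 164 genes and 4 lists. Leaving out a library gave 177 to 3629 genes and 4 to 9 lists, so replicate 1 set the merged counts. The housekeeping odds ratio was 0 among shared peaks and ran from 0 to 3.91 over the libraries left out. For histone genes it was 0.915 at −log10 q of at least 5, 0.845 by nearest gene, 0 among shared peaks and 0 to 2.19 over the libraries left out. The value of 0 comes from few genes in the short list, and the cause of the others was not tested. Without known REST targets, the neuroendocrine odds ratio was 0.79, since 8 of its 28 genes are such targets. The search for the RE1 element and its alternatives, removal of soft-masked peaks and a background of CpG-rich promoters were not run for lack of sequence. The table has 1 model per gene, so the choice of 1 start per gene changed nothing, and contigs have no placed genes, so they entered the peak and overlap counts only. No paired analysis was possible because there is 1 group. Read depth is unknown, so a gene without a replicate 2 peak was not shown to lack REST there.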

Other observations

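The gene-body assignment, the genes named in the first 2 paragraphs and the tests below were chosen after values had been seen, except the comparison within equal parts of the list by fold enrichment. Many shared peaks lay deep inside genes. Outside the regions defined as prone to repeats, 82 of 203 shared peaks were more than 5 kb from a protein-coding gene end. Of the 82, 42 lay inside a protein-coding gene. Of the genes that hold these 42 peaks, 4 were on the list of known REST targets (ATP2B2, CPLX2, L1CAM and SYT7), 4 among synaptic vesicle release genes (CPLX2, DNM1, SYT2 and SYT7) and 2 in the calcium channel family (CACNA1A and CACNA1C). These shares were not tested, and most of the 42 peaks lay in genes outside the fixed lists. The CACNA1C peak (chromosome 12, 2255817 to 2256073) had fold enrichment of 10.1 in replicate 1 and 12.8 in replicate 2, and the L1CAM peak (chromosome X, 153875468 to 153875685) 7.76 and 8.85. Against lists matched on gene length, summits of the merged set inside gene bodies were also more frequent for lists that had not passed near gene ends, namely neuronal transcription and splicing regulators (12 of 39, 4.16 expected, permutation test adjusted p = 0.00617), axon guidance and neuronal adhesion genes (15 of 39, 6.35 expected, permutation test adjusted p = 0.0116) and calcium channel genes (10 of 26, 3.92 expected, permutation test adjusted p = 0.025). Near gene ends the axon guidance list had pointed the other way, with 3 of 39 genes (odds ratio 0.37, exact adjusted p = 0.241). The protocadherin family passed too, but its count, 34 of 65, rested on 5 distinct peaks in overlapping gene models.

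Outside the regions defined as prone to repeats, shared peaks lay within 5 kb of 6 of 1911 microRNA genes. Among them were MIR137 (chromosome 1, 98048143 to 98048588, fold enrichment 6.24 and 9.10) and MIR7-3 (chromosome 19, 4769251 to 4769815, 9.93 and 8.45). Replicate 1 peaks outside these regions lay near 111 microRNA genes, among them MIR132 and MIR212 on chromosome 17, which had the same peak, of fold enrichment 7.05, in replicate 1 alone. MicroRNA genes were not tested as a group.

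Peaks near housekeeping, histone, ribosomal and RAB genes, leaving out genes also listed as known REST targets, were rarely found again in replicate 2, at 1 of 66, where 2.92 were expected from replicate 1 peaks nearest in fold rank (SD 1.51). Their low recovery was within what their strength predicts. Known REST targets had 12 of 31 found again, where 4.30 were expected (SD 1.75), and within 10 equal parts of the list by fold enrichment they were found again more often than the other genes (9.02 expected, two-sided stratified permutation p = 0.0237). That difference can come from the excess at known targets alone, so it does not exclude the loss of weak peaks, which may be the whole cause of the low recovery. If all active promoters were tagged equally and the endothelial identity genes were active, these should have had a peak at least as often as housekeeping genes. Near gene ends the endothelial identity genes had one in 5% of cases and housekeeping genes in 46.7% (Fisher's exact p = 7.36e-05). Both shares were known when this comparison was chosen, so its p-value carries little weight. By nearest gene the shares were 20% and 40% (Fisher's exact p = 0.108). Expression was not measured here and a background of CpG-rich promoters was not run, so the contrast does not exclude promoter tagging as a source of these peaks.

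The short replicate 2 list and the differing number in its peak names raise the possibility of a library of a target unrelated to REST. The replicate 2 peaks alone lay near known REST targets with an odds ratio of 35.6 (lower 95% limit 16.7). Outside the regions defined as prone to repeats, 205 of 241 overlapped replicate 1, where matched random placements reached at most 11. Repeats may remain among these peaks, and random placements do not model them. The odds ratio argues against an unrelated target. The overlap by itself cannot decide, because random placements do not show how far libraries of different targets in these cells would overlap. Lower depth and lower enrichment remain open, because read totals are not given in the files, and no biological explanation was tested.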
